A study of Mus musculus with 18 samples.

How the data were processed

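Polyadenylated RNA from mouse conditionally immortalized tubular epithelial cells (im-TEC) was measured with QuantSeq 3′ mRNA libraries, a method that reads each transcript near its 3′ end. Per the labels, the cells were treated for 48 h in 6 groups of 3 libraries each. The groups were control, transforming growth factor β (TGFβ, 10 ng/mL), nicotinamide (NAM, 1 mM), TGFβ with NAM, S-adenosyl methionine (SAM, 0.5 mM) and TGFβ with SAM.

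The deposited table holds raw counts, reads per gene and library, with whole numbers and totals that differ between the 18 libraries. Per the submitters' processing notes, STAR and HTSeq were used, without versions or strand setting. The notes name the build GRCh38, whereas all 55487 gene rows carry mouse Ensembl identifiers, so build and annotation release are not settled. Whether reads from the opposite strand were counted is not given in the sources used here. Of the identifiers, 55141 were matched to a symbol in a mouse annotation, GRCm38 (GENCODE M21), which may differ from the one used for counting. The table ends with 5 special rows, of which 2 hold reads. Reads outside genes made up 22.8% to 28.2% of all reads of a library and ambiguous reads 0.607% to 0.779%; neither was used as expression. Every floor given for a gene without reads was set at 3 counts over the group. It covers counting error alone and may be too low, because reads without molecular identifiers are not independent molecules.

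Groups were taken from the sample titles. The treatment tags of SAM replicates 2 and 3 read DIM. and LUN., in conflict with their titles, and an alternative left both libraries out. Library numbers run without a gap through the 12 libraries without SAM, then skip 6 numbers, and run on through the 6 SAM libraries. Separate preparation therefore cannot be separated from SAM treatment. Replicate numbers are not stated to mark a shared day.

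Tests used edgeR 4.0.16 in R 4.3.3 on the counts, with trimmed-mean (TMM) scaling. Genes were kept by filterByExpr with a minimum count of 10, which left 13469 genes. All 18 libraries entered 1 quasi-likelihood fit with a term per group, and 8 comparisons and 2 interactions were tested as contrasts with two-sided quasi-likelihood F tests. The Benjamini-Hochberg adjusted p was required to be under 0.05 within each comparison. An interaction is the TGFβ effect with a supplement minus the TGFβ effect without it. An exact permutation of 3 against 3 libraries cannot give a p below 0.1, so single genes were tested only in the model across all genes. Values are CPM, counts scaled to library size with TMM factors, given as mean ± SD over 3 libraries. Fold changes are fitted log2 values ± SE.

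Gene lists and comparisons were fixed before the data were examined. There were 29 lists: TGFβ targets, BMP and ID response, matrix, mesenchymal and cytoskeleton, YAP targets, epithelial, tubule identity and transport, tubular injury, senescence, p53 targets, senescence-associated secretion, proliferation, NAD metabolism, methionine cycle and polyamines, epigenetic methyltransferases, interferon response, NF-κB inflammation, fatty acid oxidation, oxidative phosphorylation, glycolysis and hypoxia, integrated stress response, unfolded protein response, NRF2 and antioxidant, cholesterol synthesis, immediate early and heat shock, and markers of fibroblasts, immune cells, endothelium and podocytes. The listed symbol Dcr2 matched no gene. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and adjustment over the lists of a comparison. Camera sets a list against all other genes. The fry test, which sets it against no change, was run beside it, and an estimated correlation was the alternative. A list with fewer than 5 tested members is given as values only.

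Genes are named by a rule. Nnmt and the NAD and methionine genes were followed in every comparison. Up to 10 genes with the largest rise and 10 with the largest fall were named among those with an adjusted p under 0.05, a mean of at least 5 CPM over the compared libraries and no overlap between the libraries of both groups, a condition that chance meets for 10% of genes. For interactions the condition on overlap was dropped and 5 genes were named each way. Predicted genes without a name were left out, and some genes the rule names are not reported here. From each list, up to 4 members with the smallest p were named, or a member that did not pass.

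TGFβ signatures were built from genes past an adjusted p of 0.05 and a log2 change of 1 in the 6 libraries of 1 supplement, and tested with camera on 6 other libraries that shared none with them, with adjustment over the 4 planned sets or the 4 added after the data were examined. Signature genes below the low-count filter in the tested libraries were left out, so the number of genes differs between tests. Alternatives were DESeq2 1.42.0, DESeq2-type size factors in edgeR, library totals, no low-count filter, a minimum count of 50, a fit on the compared groups alone, the replicate number as a block, and each library left out in turn. Sets of libraries that stood apart were left out together as an addition after the data were examined. The calling procedure was tested on simulated data with 200 changed genes of 13469. Changed genes were drawn from those at a mean of 2 CPM or more, and no simulated libraries deviated together. Recovery may be lower for weakly expressed genes or where few genes change. Between 35% and 48% of 1.5-fold changes and between 64% and 75% of 2-fold changes were recovered in the 8 comparisons, and 23% to 26% and 44% to 57% in the interactions. Wrong calls made up 2.6% to 8.9% of calls.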

Results

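The data are 18 libraries of im-TEC, mouse tubular epithelial cells immortalized with a temperature-sensitive large T antigen that interferon-γ induces. Per the labels, interferon-γ and the permissive temperature were withdrawn before the cells were seeded. The series concerns nicotinamide N-methyltransferase (NNMT), an enzyme that transfers the methyl group of SAM to NAM, in tubular senescence and fibrosis. The design crosses TGFβ, a profibrotic cytokine, with supplementation of either substrate of this enzyme. Each of the 6 groups had 3 libraries.

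Reads assigned to genes numbered 7088702, 6944559 and 5842269 in control replicates 1 to 3, and 6008585, 6416235 and 4171170 in TGFβ replicates 1 to 3. The NAM libraries held 6776196, 7717626 and 6871231 reads and the TGFβ+NAM libraries 5611708, 6512282 and 5634529. The SAM libraries held 6598108, 6380402 and 5885758 reads and the TGFβ+SAM libraries 5744088, 6215288 and 6292735. Between 15236 and 16379 genes were detected per library. The biological coefficient of variation was 0.139, and the median SE of a log2 fold change was 0.19 to 0.20 in the 8 comparisons and 0.28 in the interactions.

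On the principal components of all tested genes, PC1 held 36.4% of the variance and PC2 12.4%. NAM replicate 3 and TGFβ+NAM replicate 1 stood apart from the other libraries on PC3, at 31.9 and 30.44. Their deviations from their group means correlated at r = 0.17 across 13469 genes, against at most 0.1 for other library pairs of different groups. Across the 4168 genes at 50 CPM or more, a limit chosen after the first value was seen, r was 0.61 against at most 0.4. Genes are not independent replicates. Both libraries also had a low share of reads outside genes, 23.9% and 22.8%, against 26.6 ± 0.55% in control and 28.0 ± 0.199% in SAM (SD, n = 3).

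**Figure D1:**
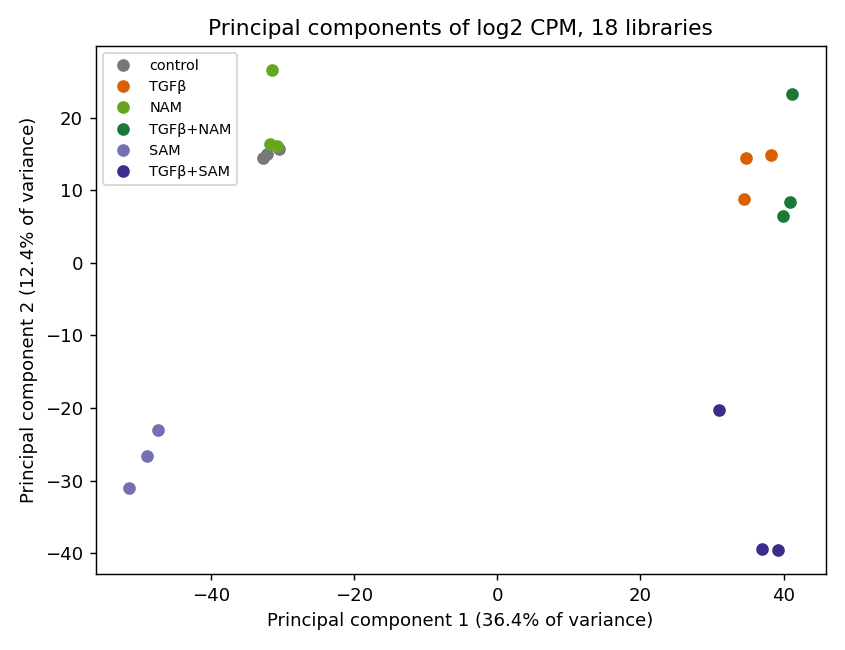
Principal components of log2 CPM, with PC1 (36.4% of the variance) on the horizontal and PC2 (12.4%) on the vertical axis, in arbitrary units. Each point is 1 of the 18 libraries, coloured by group. Libraries with TGFβ lie to the right on PC1, and SAM libraries lie low on PC2.

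Nnmt (ENSMUSG00000032271; chromosome 9, 48591877 to 48605153, minus strand in GRCm38) was measured at 30.3 ± 2.78 CPM in control, 31.1 ± 4.01 in TGFβ, 32.3 ± 0.879 in NAM and 29.0 ± 2.75 in TGFβ+NAM (SD, n = 3). It was lower in SAM, at 19.4 ± 2.20 CPM, and in TGFβ+SAM, at 19.6 ± 2.61 CPM. The log2 change was -0.65 ± 0.17 in SAM against control (adjusted p = 0.0075) and -0.67 ± 0.17 in TGFβ+SAM against TGFβ (adjusted p = 0.00908). The call against control ended without control replicate 2, with -0.58 and adjusted p = 0.0521. The call under TGFβ ended without TGFβ replicate 2, with adjusted p = 0.0787, or TGFβ+SAM replicate 1, with 0.0699. TGFβ itself left Nnmt within error, with 0.04 ± 0.16 and adjusted p = 0.918, and so did NAM, with 0.09 ± 0.16 and 0.993.

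The comparison of TGFβ with control asks what the profibrotic stimulus does in cells without a supplement. Smooth muscle actin, Acta2 (ENSMUSG00000035783), rose from 83.7 ± 9.90 to 1033 ± 50.7 CPM, a log2 change of 3.62 ± 0.10 (n = 3 against 3). Collagen I, Col1a1, rose from 5.10 ± 2.05 to 109 ± 2.91 CPM, with 4.44 ± 0.20. Among the largest rises were Ctsw, a lymphocyte cathepsin, with 6.43 ± 0.30, the imprinted transcript H19 with 5.44 ± 0.49, the metalloprotease Adam12 with 5.28 ± 0.49 and Lrrc32, a surface anchor of latent TGFβ, with 4.87 ± 0.51. Skeletal and enteric actins, Acta1 and Actg2, rose by 4.47 and 4.54, values that reads shared with Acta2 make uncertain. Inmt, an indolethylamine N-methyltransferase of the same family as Nnmt, fell from 40.9 ± 3.66 CPM to 2 reads in the TGFβ libraries together. The calcification inhibitor Mgp changed by -4.15 ± 0.38, the prostaglandin synthase Ptgds by -3.85 ± 0.27 and the chemokine scavenger Ackr3 by -3.97 ± 0.30. In total, 1307 genes were higher and 1312 lower, of which 345 and 434 by at least 2-fold. At an unadjusted p under 0.05 there were 4011 genes, where chance gives 673.

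**Figure D2:**
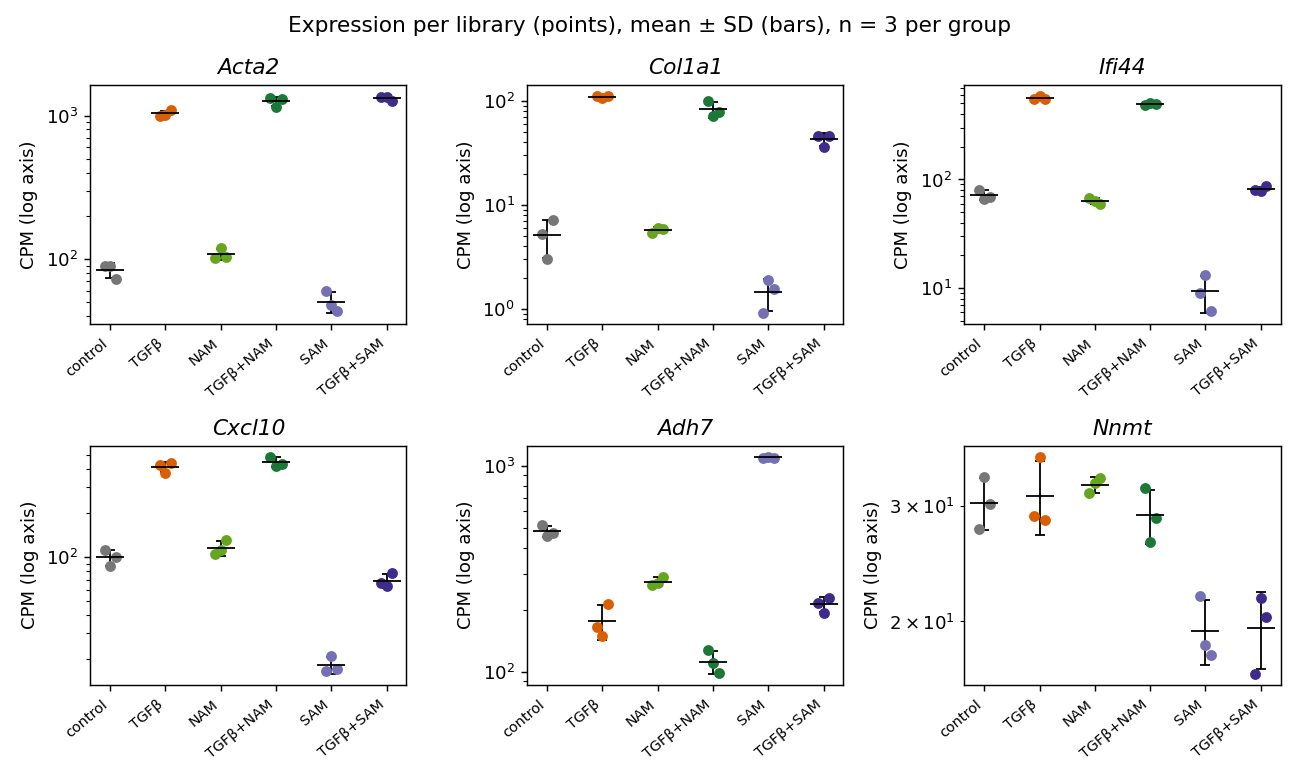
CPM per library on a log axis for Acta2, Col1a1, Ifi44, Cxcl10, Adh7 and Nnmt in the 6 groups, with bars for mean ± SD (n = 3). Acta2 rose from 83.7 to 1033 CPM with TGFβ, and Ifi44 was at 561 CPM in TGFβ and 81.7 CPM in TGFβ+SAM.

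Gene groups tied to fibrosis rose with TGFβ. Of 30 tested matrix genes, 21 were higher and 2 lower over all genes, 23 and 3 adjusted over the list alone, with a median log2 change of 1.05 (camera adjusted p = 4.27e-14); fibronectin, Fn1, rose by 1.24 ± 0.07 and periostin, Postn, by 2.11 ± 0.10. Of 23 mesenchymal and cytoskeletal genes, 13 were higher and 0 lower, 15 and 1 adjusted over the list alone (median 0.70, camera adjusted p = 5.42e-12), among them Tagln with 2.22. Of 18 TGFβ targets, 11 were higher and 1 lower, 13 and 1 adjusted over the list alone (median 0.51, camera adjusted p = 5.52e-09), and Pmepa1 and Ccn2 rose by 2.31 and 2.52. Of 15 YAP targets, 8 were higher and 1 lower in both counts, over all genes and adjusted over the list alone (median 0.26, camera adjusted p = 6.93e-06). The BMP and ID genes, which mark the opposing branch of the pathway, moved down. Of 11 tested, 1 was higher and 8 lower in both counts, adjusted over the list alone too (median -1.35, camera adjusted p = 1.41e-08), and Id2 changed by -2.22 ± 0.10.

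The interferon response was the list with the largest median rise among lists of 5 or more genes. Of 35 genes, 29 were higher and 0 lower, 31 and 0 adjusted over the list alone, with a median of 1.40 (camera adjusted p = 1.54e-24). Ifi44 (ENSMUSG00000028037) rose from 72.1 ± 7.38 to 561 ± 23.8 CPM, the ubiquitin-like Isg15 from 246 ± 19.7 to 1208 ± 97.7 CPM and the chemokine Cxcl10 from 99.9 ± 12.6 to 414 ± 30.9 CPM. The mean log2 CPM of the list was 5.77 to 6.00 in the control libraries and 7.20 to 7.23 in the TGFβ libraries.

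Metabolic and tubular genes fell with TGFβ. In oxidative phosphorylation, 0 of 30 genes were higher and 24 lower, 0 and 26 adjusted over the list alone (median -0.47, camera adjusted p = 1.65e-12). Fatty acid oxidation had 1 of 23 higher and 13 lower, 1 and 14 adjusted over the list alone (median -0.59, camera adjusted p = 3.6e-07), and its regulator Ppargc1a changed by -2.93 ± 0.14. Glycolysis and hypoxia had 1 of 25 higher and 12 lower, 1 and 17 adjusted over the list alone (median -0.57, camera adjusted p = 2.49e-08), with Aldoa at -1.41. NRF2 and antioxidant genes had 1 of 25 higher and 10 lower, 2 and 12 adjusted over the list alone (median -0.37, camera adjusted p = 6.97e-05), with Gstm1 at -3.59 ± 0.13. Of 13 genes of tubule identity and transport, 2 were higher and 9 lower in both counts, adjusted over the list alone too (median -0.60, camera adjusted p = 5.47e-06). The water channel Aqp1 fell from 1031 ± 49.2 to 106 ± 21.3 CPM and the sodium pump subunit Atp1b1 from 1068 ± 25.3 to 135 ± 16.8 CPM. Cholesterol synthesis went the other way, with 8 of 25 higher and 0 lower, 9 and 0 adjusted over the list alone (median 0.18, camera adjusted p = 0.00605).

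Senescence genes were not called by camera, and were called up by fry (adjusted p = 0.0449). Of 19, 4 were higher and 3 lower, 4 and 4 adjusted over the list alone (median 0.02, camera adjusted p = 0.896). Without NAM replicate 3 and TGFβ+NAM replicate 1 in the fit, 4 were higher and 5 lower. The cell-cycle inhibitors Cdkn1a and Cdkn2b rose, by 0.45 ± 0.10 and 0.55 ± 0.11, and cyclin D1, Ccnd1, fell from 665 to 139.8 CPM. Senescence-associated secretion had 5 of 19 genes higher and 6 lower, 6 and 6 adjusted over the list alone (median 0.06, camera adjusted p = 0.954), with rises of Il11 by 3.75 ± 0.52 and Inhba by 1.75 ± 0.11. Proliferation genes rose, 11 of 34 with 0 lower, 12 and 0 adjusted over the list alone (median 0.23, camera adjusted p = 0.000266). All 14 list calls of this comparison held with an estimated correlation, the largest adjusted p being 0.0363. In the other comparisons and interactions, list calls held with an estimated correlation except where an adjusted p of at least 0.05 with it is printed.

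The remaining lists gave no call by camera in TGFβ against control, with 1 exception. The p53 targets had 4 of 25 higher and 5 lower, 5 and 7 adjusted over the list alone (adjusted p = 0.896; median 0.07, test direction down). Epithelial genes had 2 of 13 higher and 4 lower, 3 and 4 adjusted over the list alone (adjusted p = 0.683), with a median of 0.05 and a mean of -0.11. Tubular injury had 2 of 18 higher and 7 lower in both counts, adjusted over the list alone too (adjusted p = 0.148). NF-κB inflammation had 4 of 18 higher and 7 lower in both counts, adjusted over the list alone too (adjusted p = 0.298), with a median of 0.04 and a mean of -0.32. The integrated stress response had 5 of 32 higher and 6 lower, 6 and 10 adjusted over the list alone (adjusted p = 0.656; median 0.01, test direction down). Without NAM replicate 3 and TGFβ+NAM replicate 1 in the fit, 10 of these were lower. The unfolded protein response had 1 of 20 higher and 0 lower in both counts, adjusted over the list alone too (adjusted p = 0.661), immediate early and heat shock genes 2 of 22 and 6, 2 and 8 adjusted over the list alone (adjusted p = 0.0921), and epigenetic methyltransferases 4 of 33 and 2 in both counts (adjusted p = 0.661). Against no change, fry called tubular injury (adjusted p = 9.93e-05), immediate early genes (0.000113), NF-κB inflammation (0.00113), the integrated stress response (0.00651) and epithelial genes (0.0329) lower. Immune markers were the exception, with 0 of 6 higher and 5 lower, 1 and 5 adjusted over the list alone (adjusted p = 0.00156). Both tested fibroblast markers, Col1a1 and Pdgfrb, rose, Pdgfrb resting on 38 reads in TGFβ and not called without control replicate 1 (adjusted p = 0.0548) or control replicate 3 (0.0506); neither tested endothelial marker passed, and 2 of 4 podocyte markers were higher and 1 lower.

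**Figure D3:**
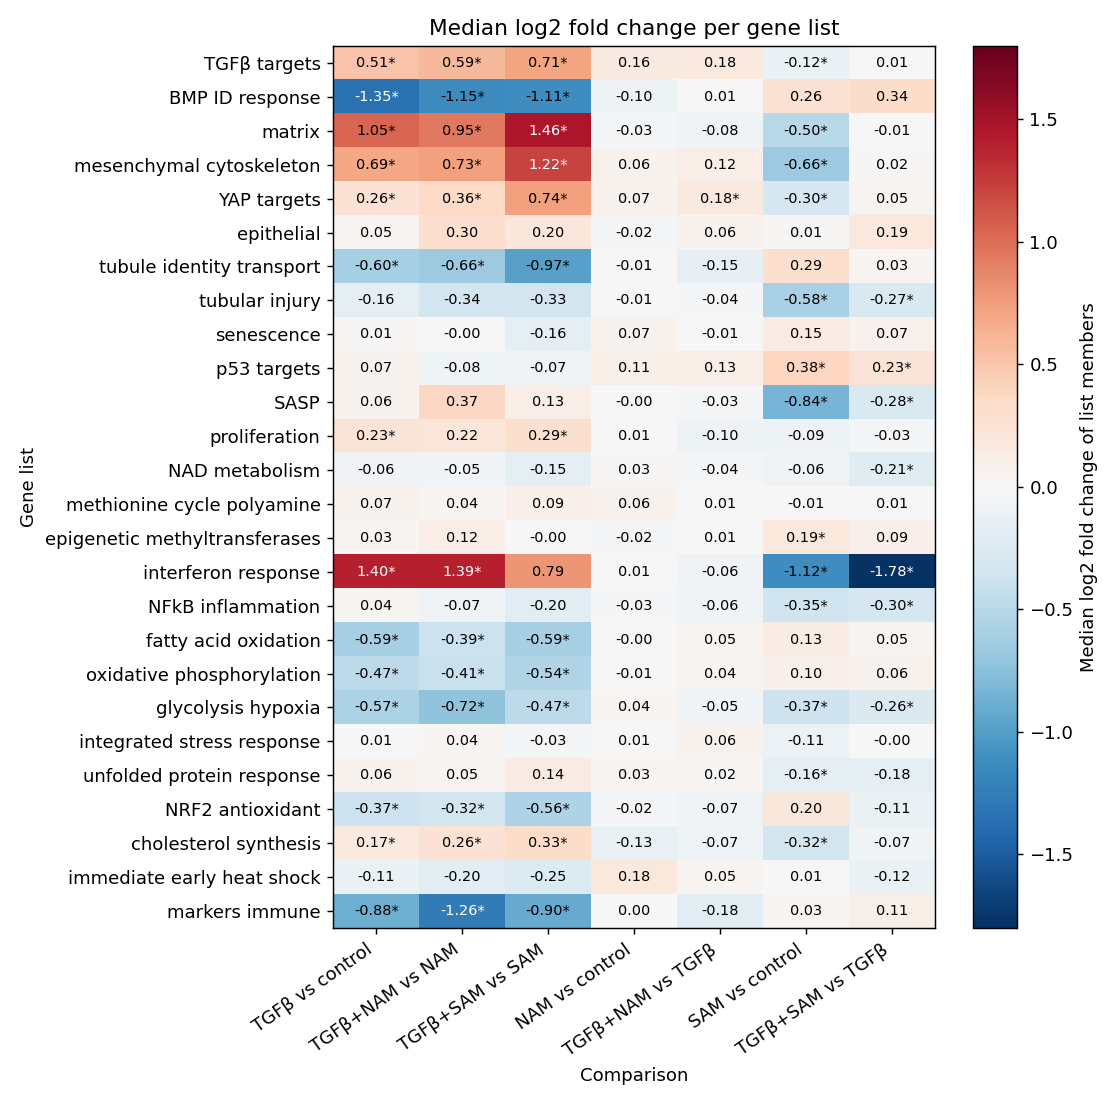
Median log2 fold change of each tested gene list (vertical) in 7 comparisons (horizontal), as colour. A star marks a camera adjusted p under 0.05 with both the preset and an estimated correlation.

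Genes of NAD and methionine metabolism moved both ways with TGFβ. NAD metabolism had 4 of 28 higher and 3 lower, 4 and 4 adjusted over the list alone (camera adjusted p = 0.896, fry adjusted p = 0.0347; median -0.06, test direction up). Its members Parp14, which is also interferon-induced, and Nampt, which salvages NAM, changed by 1.83 ± 0.11 and -0.70 ± 0.11, Nampt being chosen after its values were seen. The methionine cycle and polyamines had 4 of 28 higher and 4 lower, 4 and 5 adjusted over the list alone (median 0.07, camera adjusted p = 0.896). Methionine synthase, Mtr, rose by 0.67 ± 0.15, and ornithine decarboxylase, Odc1, changed by -0.98 ± 0.17.

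The comparison of NAM with control asks what NAM does alone. Adh7 (ENSMUSG00000055301), an alcohol and retinol dehydrogenase, fell from 481 ± 29.8 to 274 ± 12.9 CPM, a log2 change of -0.81 ± 0.10 (adjusted p = 5.16e-06, n = 3 against 3). It was the only gene called by edgeR among the 13469 genes kept by the filter, with 0 higher, and stayed the only one with each of the 6 libraries left out in turn. Without a low-count filter edgeR called 15 genes, 8 higher and 7 lower. At an unadjusted p under 0.05 there were 722 genes, against 673 by chance; DESeq2 called 17 genes, 12 of them higher. Genes of the enzyme's pathway did not pass, with Nampt at -0.16 ± 0.11 and Ahcy, which clears the product of SAM-dependent methylation, at -0.40 ± 0.36. In every list, 0 members passed over all genes. Adjusted over the list alone, higher members numbered 4 for immediate early and heat shock, 3 for mesenchymal and cytoskeleton, 2 each for matrix and tubule identity and 1 for p53 targets, and 1 NRF2 member was lower. The 4 list calls by camera all ended with an estimated correlation. They were TGFβ targets with median 0.16, adjusted p = 0.00194 and adjusted p = 0.137 with an estimated correlation, and p53 targets with 0.11, 0.00194 and adjusted p = 0.117 with an estimated correlation. Cholesterol synthesis gave -0.13, 0.00194 and adjusted p = 0.0851 with an estimated correlation, and immediate early genes 0.19, 0.00584 and adjusted p = 0.117 with an estimated correlation. At this depth, simulated 2-fold changes were recovered for 71% of genes and 1.5-fold changes for 40%.

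The comparison of SAM with control asks what SAM does alone, and includes any difference of preparation, since the SAM libraries form a separate block of library numbers. Ifi44 fell from 72.1 ± 7.38 to 9.48 ± 3.57 CPM (n = 3), Cxcl10 from 99.9 ± 12.6 to 18.2 ± 2.35 CPM and the interferon regulator Irf7 from 27.5 ± 9.12 to 5.10 ± 2.12 CPM. Siglecg, an inhibitory sialic-acid receptor, changed by -2.54 ± 0.24, the smooth-muscle calponin Cnn1 from 29.7 ± 1.32 to 4.73 ± 0.552 CPM, and Apol9b by -2.40 ± 0.16. Mgp rose from 17.8 ± 1.32 to 89.5 ± 8.99 CPM, the adhesion molecule Nectin4 by 1.85 ± 0.22, and haem oxygenase, Hmox1, from 15.2 ± 3.39 to 47.0 ± 4.41 CPM. In total, 676 genes were higher and 915 lower, of which 57 and 194 by at least 2-fold, and 3258 passed an unadjusted p under 0.05. With SAM replicates 2 and 3 left out for their conflicting tags, 466 genes were called.

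Fibrosis and inflammation genes were lower in SAM than in control. The interferon response had 1 of 35 higher and 28 lower, 1 and 29 adjusted over the list alone (median -1.12, camera adjusted p = 3.66e-27). Mesenchymal and cytoskeletal genes had 1 of 23 higher and 15 lower, 1 and 17 adjusted over the list alone (median -0.66, camera adjusted p = 1.63e-13), with S100a4 at -1.40 ± 0.10. Matrix genes had 0 of 30 higher and 11 lower, 1 and 14 adjusted over the list alone (median -0.50, camera adjusted p = 5.64e-07), with Postn at -1.55 ± 0.11 and Col1a1 at -1.79 ± 0.32. TGFβ targets had 0 of 18 higher and 7 lower, 1 and 8 adjusted over the list alone (median -0.12, camera adjusted p = 0.000858, and adjusted p = 0.0498 with an estimated correlation). YAP targets had 2 of 15 higher and 6 lower, 2 and 7 adjusted over the list alone (median -0.30, camera adjusted p = 0.00375). Tubular injury had 1 of 18 higher and 10 lower, 2 and 13 adjusted over the list alone (median -0.58, camera adjusted p = 5.64e-07). Senescence-associated secretion had 0 of 19 higher and 9 lower, 0 and 10 adjusted over the list alone (median -0.84, camera adjusted p = 5.64e-07), with Ccl2 at -1.07 ± 0.14. NF-κB inflammation had 0 of 18 higher and 8 lower, 1 and 9 adjusted over the list alone (median -0.35, camera adjusted p = 0.000233). Cholesterol synthesis had 0 of 25 higher and 11 lower in both counts, adjusted over the list alone too (median -0.32, camera adjusted p = 1.14e-06).

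The p53 targets were higher in SAM than in control. Of 25, 11 were higher and 0 lower, 13 and 0 adjusted over the list alone (median 0.38, camera adjusted p = 6.37e-07), with Trp53inp1 at 0.59 ± 0.09 and Mdm2 at 0.49 ± 0.08. Senescence genes were not called by camera or fry (fry adjusted p = 0.954), with 3 of 19 higher and 2 lower, 4 and 3 adjusted over the list alone (camera adjusted p = 0.437), or 5 and 3 without NAM replicate 3 and TGFβ+NAM replicate 1 in the fit. Glycolysis and hypoxia had 2 of 25 higher and 9 lower, 2 and 10 adjusted over the list alone (median -0.37, camera adjusted p = 0.00022), the unfolded protein response 0 of 20 and 5 in both counts, adjusted over the list alone too (median -0.16, camera adjusted p = 0.00029), and epigenetic methyltransferases 4 of 33 and 1, 5 and 3 adjusted over the list alone (median 0.19, camera adjusted p = 0.00832). Other calls ended with an estimated correlation. BMP and ID genes had 4 of 11 higher (camera adjusted p = 0.0245, adjusted p = 0.0985 with an estimated correlation) and tubule identity 5 of 13 higher (0.0366, adjusted p = 0.0634 with an estimated correlation). Oxidative phosphorylation had 4 of 30 higher (0.0117, adjusted p = 0.21 with an estimated correlation) and NRF2 genes 6 of 25 higher and 4 lower (0.0352, adjusted p = 0.211 with an estimated correlation). The rate-limiting enzyme of glutathione synthesis, Gclc, rose by 1.08 ± 0.10. Methionine genes moved both ways, with 4 of 28 higher and 4 lower in both counts, adjusted over the list alone too (camera adjusted p = 0.638). Mat2a, which makes SAM, fell from 263 ± 8.38 to 179 ± 5.60 CPM, a log2 change of -0.55 ± 0.09, and Mtr rose by 0.71 ± 0.15. NAD metabolism had 1 of 28 higher and 6 lower in both counts, adjusted over the list alone too (camera adjusted p = 0.0804, fry adjusted p = 7.77e-05), and Nampt went from 132 ± 10.5 to 185 ± 11.9 CPM.

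The comparison of TGFβ+NAM with TGFβ asks whether NAM changes the TGFβ-treated state. Adh7 fell from 176 ± 34.0 to 112 ± 14.2 CPM (adjusted p = 0.00138, n = 3 against 3) and nephronectin, Npnt, from 37.6 ± 4.54 to 18.2 ± 3.43 CPM (adjusted p = 0.00138). Neither lost its call with any library of both groups left out. The immediate early gene Egr1 rose by 0.62 ± 0.11 (adjusted p = 0.00752) and the thioredoxin inhibitor Txnip by 0.56 ± 0.11. The matricellular genes Ccn1 and Ccn2, targets of YAP, rose by 0.33 ± 0.07 and 0.38 ± 0.08, and Rbm47, Lgals3 and Sept4 changed by -0.57 ± 0.11, -0.46 ± 0.09 and -0.65 ± 0.14. The calcium-binding S100g, with 5.38 ± 1.26 CPM in TGFβ and 0.860 ± 0.532 in TGFβ+NAM (adjusted p = 0.00138), and the adenosine receptor Adora1 (adjusted p = 0.0239) complete the 11 genes called. Both lie under the expression limit for naming and were chosen after their values were seen.

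Of these 11 genes, 4 were higher and 7 lower, and 932 passed an unadjusted p under 0.05. DESeq2 called 36 genes and a fit on the compared groups alone called 0. The count was 6 without TGFβ replicate 1, 3 without TGFβ replicate 2, 5 without TGFβ replicate 3 and 6 without TGFβ+NAM replicate 2, and 20 with NAM replicate 3 and TGFβ+NAM replicate 1 left out together. Egr1 was not called without TGFβ replicate 2 (adjusted p = 0.0857) or 3 (0.0981), and Txnip not without TGFβ replicate 2 (0.0907), TGFβ replicate 3 (0.24) or TGFβ+NAM replicate 1 (0.0948). Rbm47 and Sept4 were not called without TGFβ replicate 1 or 2 or TGFβ+NAM replicate 2 or 3, Ccn2 without any library but TGFβ+NAM replicate 1, and Lgals3 and Ccn1 without any of the 6 libraries. Their adjusted p then lay between 0.0579 and 0.437. Ccn1 was also not called with the replicate number as a block (0.0587) or library totals (0.0602).

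Among lists, YAP targets had 2 of 15 higher and 0 lower with NAM under TGFβ, 4 and 0 adjusted over the list alone (median 0.18, camera adjusted p = 0.000236, and adjusted p = 0.0314 with an estimated correlation). TGFβ targets had 1 of 18 higher and 0 lower, 2 and 0 adjusted over the list alone (median 0.18, camera adjusted p = 2.47e-05), with adjusted p = 0.0545 with an estimated correlation. Mesenchymal genes had 0 of 23 calls by edgeR (median 0.13, 0.0136, adjusted p = 0.178 with an estimated correlation) and p53 targets 0 of 25 (median 0.13, 0.0173, adjusted p = 0.178 with an estimated correlation). Proliferation genes had 0 of 34 over all genes and 3 lower adjusted over the list alone (median -0.10, 0.0111, adjusted p = 0.188 with an estimated correlation). No call by camera was made for the interferon response (adjusted p = 0.301), matrix (0.856), senescence (0.856), NAD metabolism (0.856) or methionine genes (0.689).

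The comparison of TGFβ+SAM with TGFβ asks whether SAM changes the TGFβ-treated state, with the same limit of a separate block of library numbers. Interferon-induced genes were lower. Ifi44 fell from 561 ± 23.8 to 81.7 ± 4.11 CPM (n = 3), Cxcl10 from 414 ± 30.9 to 69.0 ± 7.31 CPM, the nucleic-acid sensor Zbp1 from 41.7 ± 2.84 to 2.73 ± 1.89 CPM, and Oas3 and Irf7 changed by -3.71 ± 0.31 and -3.14 ± 0.20. The near-identical paralogs Ifit3 and Ifit3b changed by -3.18 ± 0.14 and -3.44 ± 0.19, values that shared reads make uncertain for either gene alone. S100g rose by 2.12 ± 0.29, the Notch ligand Jag2 by 1.76 ± 0.32, the vitamin D-binding protein Gc by 1.89 ± 0.35 and Nectin4 from 21.5 ± 2.33 to 68.4 ± 9.67 CPM. In total, 413 genes were higher and 573 lower, 46 and 175 by at least 2-fold, and 2724 passed an unadjusted p under 0.05. The count of 986 was 653 without TGFβ replicate 3, 630 without TGFβ+SAM replicate 1 and 653 without TGFβ+SAM replicate 2.

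Of 35 interferon-response genes, 0 were higher and 34 lower with SAM under TGFβ, 0 and 35 adjusted over the list alone (median -1.78, camera adjusted p = 5.4e-60). Mean log2 CPM of the list was 5.20, 5.24 and 5.59 in TGFβ+SAM replicates 1 to 3, so replicate 3 stood closest to the TGFβ libraries. NF-κB inflammation had 0 of 18 higher and 6 lower, 0 and 7 adjusted over the list alone (median -0.30, camera adjusted p = 0.000114), secretion 1 of 19 and 9, 1 and 10 adjusted over the list alone (median -0.28, camera adjusted p = 0.000331), and tubular injury 1 of 18 and 5, 2 and 11 adjusted over the list alone (median -0.27, camera adjusted p = 0.000249). Their shared member Ccl2 changed by -1.34 ± 0.15. Without NAM replicate 3 and TGFβ+NAM replicate 1 in the fit, 2 tubular injury genes were higher and 8 lower. NAD metabolism had 0 of 28 higher and 8 lower, 1 and 9 adjusted over the list alone (median -0.21, camera adjusted p = 7.61e-05), with the interferon-induced Parp14 at -2.04 ± 0.11 and Parp9 at -1.34 ± 0.12. Glycolysis had 0 of 25 higher and 8 lower, 0 and 10 adjusted over the list alone (median -0.26, camera adjusted p = 0.000128). The p53 targets were higher here too, 7 of 25 with 0 lower, 9 and 0 adjusted over the list alone (median 0.23, camera adjusted p = 0.000114), with Mdm2 at 0.46 ± 0.08 and Zmat3 at 0.50 ± 0.08. The unfolded protein response, with 0 of 20 higher and 4 lower, gave a camera adjusted p = 0.00297 and adjusted p = 0.0678 with an estimated correlation. Epithelial genes, with 1 of 13 higher, gave 0.0411 and adjusted p = 0.0678 with an estimated correlation.

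Fibrosis genes as groups were not called lower by camera with SAM under TGFβ, whereas fry called mesenchymal genes lower (adjusted p = 0.0389), with members going both ways. Matrix genes had 3 of 30 higher and 4 lower, 5 and 5 adjusted over the list alone (camera adjusted p = 0.531), mesenchymal genes 1 of 23 and 4, 2 and 6 adjusted over the list alone (0.367; median 0.02, test direction down), and TGFβ targets 1 of 18 and 0 in both counts, adjusted over the list alone too (0.306). Without NAM replicate 3 and TGFβ+NAM replicate 1 in the fit, mesenchymal genes had 3 higher and 6 lower and matrix genes 5 higher and 4 lower. Single members moved in opposite directions. Col1a1 fell from 109 ± 2.91 to 42.9 ± 5.94 CPM and S100a4 from 329.8 ± 13.5 to 146 ± 4.13 CPM, while Pmepa1 rose by 0.43 ± 0.09. Senescence genes had 3 of 19 higher and 1 lower, 3 and 2 adjusted over the list alone (0.306, fry adjusted p = 0.0389), and methionine genes 1 of 28 and 1 in both counts, adjusted over the list alone too (0.912), with Mat2a at -0.60 ± 0.09. The calls of the senescence genes Lmna, Trp53 and Gdf15 ended with 1 library left out for 6, 5 and 2 libraries, with adjusted p up to 0.175.

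The direct comparison of TGFβ+NAM with TGFβ+SAM tests whether both supplements differ under TGFβ. Zbp1 stood at 36.5 ± 2.00 CPM with NAM and 2.73 ± 1.89 with SAM (n = 3), Usp18 and Irf7 were higher with NAM by 3.00 ± 0.20 and 2.91 ± 0.20, and S100g and Jag2 were lower with NAM, by -4.74 ± 0.37 and -2.12 ± 0.32. In total, 602 genes were higher and 495 lower, 165 and 73 by at least 2-fold, and 2822 passed an unadjusted p under 0.05. With library totals, 530 were higher and 558 lower. The count of 1097 was 696 without TGFβ+SAM replicate 1, 705 without TGFβ+SAM replicate 2 and 667 in a fit on the compared groups alone. Of 35 interferon-response genes, 34 were higher with NAM and 0 lower, 35 and 0 adjusted over the list alone (median 1.61, camera adjusted p = 1.36e-57). NAD metabolism had 9 of 28 higher and 0 lower in both counts, adjusted over the list alone too (median 0.22, camera adjusted p = 4.34e-05). Further lists called higher with NAM were secretion (camera adjusted p = 0.00159), tubular injury (0.00252), glycolysis (0.00049), the unfolded protein response (0.000471), immediate early genes (0.00254) and NF-κB inflammation (0.00561). Calls ended for BMP and ID genes, 0 of 11 higher and 4 lower (camera adjusted p = 0.00947, adjusted p = 0.0736 with an estimated correlation), mesenchymal genes, 6 of 23 and 1 (0.0142, adjusted p = 0.113), and epithelial genes, 0 of 13 and 2 (0.0231, adjusted p = 0.0508). They also ended for p53 targets, 0 of 25 and 5 (0.032, adjusted p = 0.13), and the integrated stress response, 4 of 32 and 1 (0.0372, adjusted p = 0.0508). Nnmt was higher with NAM by 0.57 ± 0.17 (adjusted p = 0.0292), a call that ended without TGFβ+NAM replicate 1 (0.13), TGFβ+NAM replicate 3 (0.0603) or TGFβ+SAM replicate 1 (0.156).

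The comparison of TGFβ+NAM with NAM gives the TGFβ effect on a NAM background. Acta2 rose from 108 ± 9.41 to 1257 ± 97.7 CPM (n = 3) and Ctsw by 5.17 ± 0.25, while Gstm1 and Aqp1 changed by -4.16 ± 0.13 and -3.77 ± 0.11. Inmt had 0 reads in TGFβ+NAM, at least 258-fold lower than in NAM by a floor of 3 counts over the group, which covers counting error alone. In total, 1465 genes were higher and 1481 lower, 409 and 530 by at least 2-fold, and 4283 passed an unadjusted p under 0.05. With library totals, 1206 were higher and 1722 lower. Matrix genes had 21 of 30 higher and 1 lower, 22 and 1 adjusted over the list alone (median 0.95, camera adjusted p = 5.25e-13), the interferon response 28 of 35 and 0, 29 and 0 adjusted over the list alone (median 1.39, camera adjusted p = 5.51e-20) and oxidative phosphorylation 0 of 30 and 24, 0 and 25 adjusted over the list alone (median -0.41, camera adjusted p = 1.51e-10). Proliferation (camera adjusted p = 0.0343) ended with adjusted p = 0.208 with an estimated correlation, and immediate early genes (0.0143) with adjusted p = 0.0716 with an estimated correlation. The interaction of NAM with TGFβ tests whether the TGFβ response differs with NAM. It called 0 genes by edgeR and 0 by DESeq2, and 462 passed an unadjusted p under 0.05, against 673 by chance. The smallest list adjusted p was 0.335. Simulated 2-fold interactions were recovered for 57% of changed genes, with the limits of the simulation given above.

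The comparison of TGFβ+SAM with SAM gives the TGFβ effect on a SAM background. Acta1 rose from 3.91 ± 0.640 to 282 ± 30.8 CPM (n = 3), again uncertain from reads shared with Acta2, and Il1rl1, the interleukin-33 receptor, by 6.04 ± 0.35, while Mgp and the glycoprotein hormone Stc1 changed by -6.40 ± 0.34 and -4.74 ± 0.46. In total, 1910 genes were higher and 1914 lower, 545 and 709 by at least 2-fold, and 5046 passed an unadjusted p under 0.05. With SAM replicates 2 and 3 left out the count was 2258. Matrix genes had 23 of 30 higher and 2 lower, 25 and 3 adjusted over the list alone (median 1.46, camera adjusted p = 4.39e-16) and mesenchymal genes 20 of 23 and 0, 20 and 1 adjusted over the list alone (median 1.22, camera adjusted p = 3.79e-16). The interferon response had 21 of 35 higher and 5 lower in both counts, adjusted over the list alone too (median 0.79, camera adjusted p = 2.63e-05), with adjusted p = 0.123 with an estimated correlation. Immediate early genes gave 0.0136, with adjusted p = 0.0722 with an estimated correlation.

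The interaction of SAM with TGFβ tests whether the TGFβ response differs with SAM. Tnnt2, cardiac troponin T, rose with TGFβ from 38.4 ± 3.79 to 190.4 ± 22.4 CPM without SAM and from 8.95 ± 2.50 to 262 ± 27.7 CPM with it, an interaction of 2.55 ± 0.19 (n = 3 per group). The basement-membrane collagen Col4a4 rose from 5.72 ± 2.10 to 44.5 ± 1.91 CPM without SAM and from 0.830 ± 0.613 to 45.6 ± 7.51 CPM with it, an interaction of 2.78 ± 0.50. Postn gave 1.85 ± 0.15, Cnn1 1.89 ± 0.25 and Acta2 1.09 ± 0.14. Ifit3 went from 64.6 ± 1.43 to 181 ± 19.2 CPM without SAM and from 59.7 ± 4.92 to 19.8 ± 6.91 CPM with it, an interaction of -3.07 ± 0.19, and the stress factor Atf3 gave -2.10 ± 0.32. In total, 108 genes had a higher and 85 a lower signed log2 TGFβ effect with SAM, 48 and 30 by at least 2-fold, and 1403 passed an unadjusted p under 0.05. With SAM replicates 2 and 3 left out, 63 genes were called. Of the 108 genes, 89 were lower in SAM than in control, and 79 were not called between TGFβ+SAM and TGFβ. Of the 85 genes, 52 were lower in TGFβ+SAM than in TGFβ.

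Mesenchymal genes had 9 of 23 with a higher TGFβ effect under SAM and 0 with a lower, 12 and 0 adjusted over the list alone (median interaction 0.41, camera adjusted p = 1.9e-14). Matrix genes had 4 of 30 and 0, 9 and 0 adjusted over the list alone (median 0.40, camera adjusted p = 1.17e-07), TGFβ targets 4 of 18 and 0, 6 and 0 adjusted over the list alone (median 0.27, camera adjusted p = 2.8e-06), YAP targets 5 of 15 and 0, 6 and 1 adjusted over the list alone (median 0.27, camera adjusted p = 2.98e-06), and cholesterol synthesis 1 of 25 and 0 in both counts, adjusted over the list alone too (median 0.25, camera adjusted p = 0.000894). The TGFβ effect was lower in the interferon list, with 0 of 35 higher and 8 lower, 0 and 21 adjusted over the list alone (median -0.58, camera adjusted p = 1.66e-16). Without TGFβ+SAM replicate 3, 13 were lower and the median was -0.68. NAD metabolism had 0 of 28 higher and 3 lower, 0 and 6 adjusted over the list alone (median -0.16, camera adjusted p = 0.0108), with Nampt at -1.01 ± 0.16. NRF2 genes had 0 of 25 and 3, 0 and 9 adjusted over the list alone (median -0.31, camera adjusted p = 0.000115), with adjusted p = 0.054 with an estimated correlation; without NAM replicate 3 and TGFβ+NAM replicate 1 in the fit, 5 were lower. TGFβ lowers NRF2 genes as a group, so a lower effect here is a larger fall. Senescence (camera adjusted p = 0.674) and methionine genes (0.687) were not called.

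**Figure D4:**
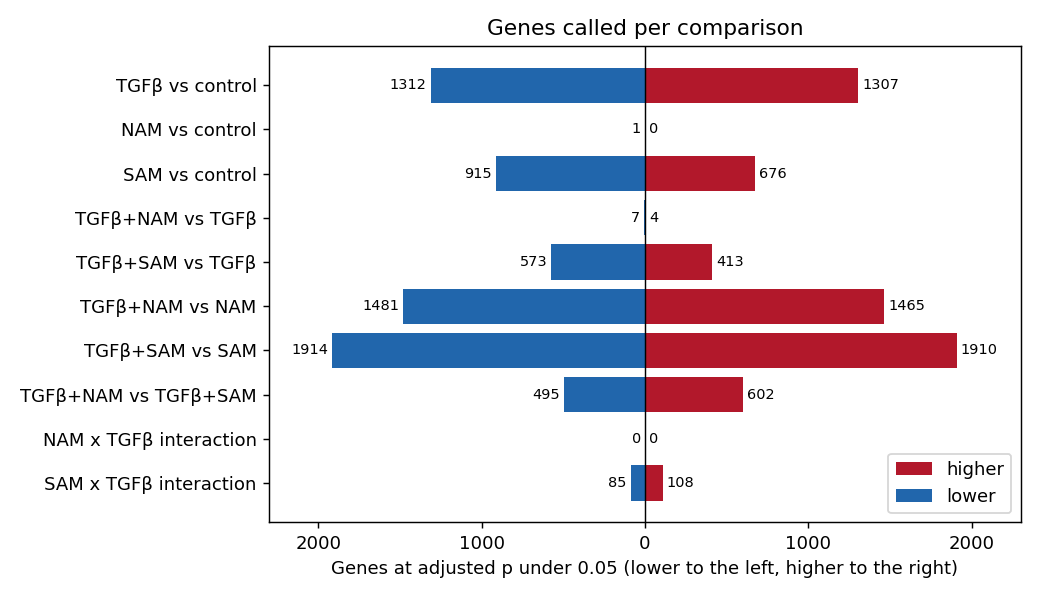
Number of genes called higher and lower by edgeR (adjusted p under 0.05, of 13469 tested) in the 8 comparisons and 2 interactions. NAM against control gave 1 gene and SAM against control 1591.

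TGFβ signatures from libraries not used in the tested pair asked whether a supplement shifts the TGFβ-treated state as a whole. The 441 genes raised by TGFβ on the SAM background had a median log2 change of 0.07 in TGFβ+NAM against TGFβ, 60.1% of them higher (camera adjusted p = 0.00558, and adjusted p = 0.204 with an estimated correlation); without TGFβ replicate 2 the adjusted p was 0.0956. The 556 lowered genes had a median of -0.10 (camera adjusted p = 0.00252, and adjusted p = 0.0824 with an estimated correlation). In TGFβ+SAM against TGFβ, the 372 genes raised by TGFβ on the NAM background had a median of -0.03 (camera adjusted p = 0.00976, and adjusted p = 0.204 with an estimated correlation) and the 411 lowered genes -0.06 (camera adjusted p = 0.14). The lowered genes had -0.089 without TGFβ replicate 1, -0.099 without TGFβ replicate 2 and -0.105 without TGFβ+SAM replicate 3 (adjusted p = 0.0848). Without TGFβ+SAM replicate 3 the raised genes had a median of 0.02 with adjusted p = 0.0867 and a test direction still down, and without TGFβ replicate 3 their adjusted p = 0.0605. Fry, run beside camera, gave unadjusted p of 0.135 for raised and 0.0311 for lowered genes in TGFβ+NAM against TGFβ. With the replicate number as a block, fry gave 0.32 and 0.0641. In TGFβ+SAM against TGFβ, fry gave 0.00182 for raised and 0.237 for lowered genes, and 0.0324 and 0.432 with the block.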

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

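For the lower interferon genes, the tests of scaling, of separate handling and of the share of reads outside genes in cells without TGFβ were chosen only after the result was seen. So were the tests of a constant shift, of low counts and of 1 deviating library for the TGFβ response with SAM, and both tests of the libraries that stood apart. The p-values of edgeR and fry measure the spread between these libraries, which may be technical if replicates were wells of 1 culture. Camera p-values set the genes of a list against all other genes at an assumed correlation. They are therefore not a measure of the spread between replicates. In every comparison of SAM with SAM-free groups, separate handling of the SAM libraries cannot be told apart from SAM itself, because 0 SAM-free libraries are numbered inside the SAM block.

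The TGFβ response differed between cells with and without SAM for 193 genes. The signed TGFβ effect was higher with SAM for Col4a4 (log2 interaction 2.78), Tnnt2 (2.55), Adcy7 (2.30) and Il1rl1 (2.17), and lower for Ifit3b (-3.21), Ifit3 (-3.07), Cox7a1 (-2.97), Cxcl5 (-2.16) and Adra1b (-2.13). Of these, Adcy7, Il1rl1, Cox7a1, Cxcl5 and Adra1b were no longer called with 1 library left out for 4 to 9 of the 12 libraries, with adjusted p up to 0.187, and Adra1b also not with the replicate number as a block (0.0547) or library totals (0.0572). List medians of the interaction were 0.27 for TGFβ targets, 0.40 for matrix, 0.41 for mesenchymal and cytoskeletal genes, 0.27 for YAP targets and 0.25 for cholesterol synthesis. They were -0.155 for NAD metabolism, -0.58 for the interferon response and -0.31 for NRF2 genes, the last with adjusted p = 0.054 with an estimated correlation.

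For the larger TGFβ response with SAM, a constant shift of the SAM libraries would cancel in the interaction, whereas 375 genes raised by TGFβ on the NAM background, libraries the interaction does not use, had a median interaction of 0.41, with 68.3% above 0. The 102 of these genes at a mean of 50 CPM or more over all libraries also had a median of 0.41, with 76.5% above 0. Genes raised by TGFβ can pass that limit through the TGFβ groups, so low counts in cells without TGFβ stay open. A cause in 1 deviating library is argued against. Without TGFβ+SAM replicate 3, 237 genes were called, and at least 131 without any 1 of the 12 libraries. Other splits of the samples do not exclude chance and cannot decide on it. They exchange SAM and SAM-free libraries within each background, which mixes SAM effects into the interaction. Of 40 splits, the real one included, 2 gave at least 193 genes, and the highest other gave 650. That split exchanged all 3 libraries between SAM and control and 1 between both TGFβ groups, so it adds up the SAM effects of both backgrounds, a structure of the samples. Of the 108 genes with a positive interaction, 89 were lower in SAM than in control, and 22 were higher and 7 lower in TGFβ+SAM than in TGFβ; an effect of SAM itself and separate handling of the SAM libraries both stay open.

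Interferon-response genes were lower in SAM libraries without and with TGFβ, with list medians of -1.12 and -1.78. Scaling of the libraries is argued against, since a scale factor moves all genes alike, whereas at most 3.4% of other genes lay below the list median in either comparison. As many genes were lower with the share of reads outside genes as a covariate as without it. These were 34 of 35 in TGFβ+SAM against TGFβ and 28 of 35 in SAM against control. The fit holds a term per group, so its slope comes from spread within groups and may miss a shift of all SAM libraries. Values per library, read after the result, argue against this share under TGFβ. TGFβ+NAM replicates 1 to 3 had shares of 22.8%, 27.3% and 26.8% and list means of 7.10, 7.14 and 7.15 log2 CPM. TGFβ+SAM replicates 1 to 3 had 26.6%, 26.3% and 25.9%, and 5.20, 5.24 and 5.59. Without TGFβ, the share of every SAM library lay above control, so it stays open there. Separate handling of the SAM libraries stays open, with 0 SAM-free libraries numbered in their block. Genes detected numbered 15376 ± 94.0 in SAM and 16137 ± 135 in control (SD). In TGFβ+SAM they numbered 15236, 15273 and 15999 in replicates 1 to 3, replicate 3 having the highest interferon mean. Whether this measure bears on the pattern was not tested. An effect of SAM on these genes may explain the pattern, and the design has no library that would part it from a preparation effect.

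NAM replicate 3 and TGFβ+NAM replicate 1 deviated together although they belong to different groups. Transcript length is argued against, since the weaker of both rank correlations between a gene's deviation and its transcript length was -0.10 across genes, which are not independent replicates. The share of reads outside genes may mark the source, since both, 2 of 2, had the lowest share of their group. No biological explanation was tested. Reads outside genes also stood out in the 3 libraries with SAM alone, at 28.0% of reads against 26.6% in control, and TGFβ+SAM, at 26.27%, lay above TGFβ, at 25.41%.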

How the results depend on the processing

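Leaving out NAM replicate 3 and TGFβ+NAM replicate 1 together, and the TGFβ signatures on SAM or NAM against control, were chosen only after the data were examined. All 10 counts of called genes stayed within 1.5 times their value with DESeq2-type size factors, library totals, a minimum count of 50 and the replicate number as a block, though library totals changed the balance of higher and lower genes, to 1145 and 1433 for TGFβ against control. Without a low-count filter, NAM against control gave 15 genes and TGFβ+NAM against TGFβ 32; with DESeq2 they gave 17 and 36. In a fit on the compared groups alone, TGFβ+NAM against TGFβ gave 0 by edgeR and TGFβ+NAM against TGFβ+SAM 667, whereas SAM against control rose to 2383, TGFβ against control to 3188 and the SAM interaction to 252. With SAM replicates 2 and 3 left out, which leaves 1 library assumed to vary like the other groups, SAM against control gave 466 genes, TGFβ+SAM against SAM 2258 and the SAM interaction 63. With NAM replicate 3 and TGFβ+NAM replicate 1 left out, TGFβ+NAM against TGFβ gave 20. Where no construction shows it, the cause was not tested.

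With 1 library left out in turn, counts ranged from 3 to 14 for TGFβ+NAM against TGFβ, 630 to 1068 for TGFβ+SAM against TGFβ, and 696 to 1192 for TGFβ+NAM against TGFβ+SAM. The other 7 counts stayed within 1.5 times their value, with 131 to 237 for the SAM interaction and 1 throughout for NAM against control.

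The signature from the SAM background in TGFβ+NAM against TGFβ, without a fold limit, gave 0.014 for raised and -0.025 for lowered genes (adjusted p = 0.188 for each). With an estimated correlation the raised genes, at 0.067, had adjusted p = 0.204 and the lowered genes, at -0.101, adjusted p = 0.0824. With 1 library left out the raised genes ranged from 0.054 to 0.106. The signature from the NAM background in TGFβ+SAM against TGFβ gave -0.013 for raised genes without a fold limit (adjusted p = 0.188), and -0.027 with adjusted p = 0.204 with an estimated correlation. With 1 library left out the raised genes ranged from -0.06 to 0.021 and the lowered genes from -0.105 to -0.044. In NAM against control, genes of the SAM background raised by TGFβ had a median of -0.006 with a test direction up. That direction was down without a fold limit (-0.008) and without NAM replicate 3 (0.008). The median itself was above 0 with library totals (0.018) and with control replicate 2 or 3 or any NAM library left out, ranging from -0.004 to 0.019 with 1 library left out. The cause was not tested.

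Direction was followed for Nnmt and for named genes called in the comparison, and of these only Nnmt, near 0, turned direction. Other named genes without a call were not followed. Its SAM interaction was 0.012 with library totals and ranged from -0.101 to 0.093 with 1 library left out, above 0 without control replicate 1, TGFβ replicate 2, SAM replicate 1 or TGFβ+SAM replicate 1. It ranged from -0.079 to 0.109 in TGFβ against control, below 0 without control replicate 1 or TGFβ replicate 2, and from -0.176 to 0.012 in TGFβ+NAM against TGFβ, above 0 without TGFβ replicate 2. In TGFβ+SAM against SAM it ranged from -0.062 to 0.12, below 0 without SAM replicate 2 or 3 or TGFβ+SAM replicate 2 or 3. The called named genes kept their direction. Among 4620 values of the genes followed, 368 calls ended with 1 library left out. Another 11 ended with library totals, 10 with DESeq2 and 4 with the replicate number as a block. Of 260 list tests, 24 calls ended with an estimated correlation.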

Other observations

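The average NAM effect, the overlap of SAM effects and the TGFβ signatures on single supplements were chosen only after the data were examined, whereas the test of opposite effects of both supplements was planned before its result was seen. Averaged over cells with and without TGFβ, NAM changed 46 genes, 21 higher and 25 lower. This contrast holds NAM replicate 3 and TGFβ+NAM replicate 1, which deviated together, on its NAM side; without both, 33 genes were called, 21 of them shared. With 1 library left out the count ranged from 12 without control replicate 3 to 55 without NAM replicate 2. It was also below 46 by over 1.5 times without control replicate 1 (18) or 2 (22), TGFβ replicate 1 (29), 2 (16) or 3 (27), NAM replicate 1 (30) or NAM replicate 3 (17). Adh7 changed by -0.73 ± 0.07 (adjusted p = 1.75e-08), S100g by -1.59 ± 0.25 and Npnt by -0.60 ± 0.11. Egr1 rose by 0.52 ± 0.07 and Txnip by 0.51 ± 0.08, and the glutathione enzyme Gclm changed by -0.32 ± 0.06. These 6 genes were called in each of those fits. Acta2 and Ccn2, followed in the same way, were not, with adjusted p of 0.108 and 0.138 without control replicate 3. With SAM, S100g was at 23.4 ± 4.85 CPM in TGFβ+SAM against 5.38 ± 1.26 in TGFβ, without a call in SAM against control (0.41 ± 0.26, adjusted p = 0.355). Adh7 was at 1096 ± 10.8 CPM in SAM against 481 ± 29.8 in control, without a call in TGFβ+SAM against TGFβ (0.28 ± 0.10, adjusted p = 0.0887), values chosen after they were seen. The average SAM effect covered 2463 genes, 1105 higher and 1358 lower.

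SAM had partly like effects in cells with and without TGFβ, measured on libraries that share none. Genes that respond to TGFβ on the NAM background were an exception. The raised genes had a median of -0.587 in SAM against control and -0.027 in TGFβ+SAM against TGFβ. The lowered genes had 0.169 and -0.056. Of the genes higher in SAM against control and in TGFβ+SAM against TGFβ, 197 were shared, where independent lists would share 20.7, and 284 of the lower genes, against 38.9. Across 13469 genes the correlation of both effects was 0.34, and 0.51 across the 10533 genes at 5 CPM or more; genes are not independent replicates. For NAM the correlation was 0.12, and 0.19 at 5 CPM or more, and Adh7 was the only shared gene. Each NAM effect holds 1 of the 2 libraries that deviated together, and without both the correlation was 0.06, and 0.1 at 5 CPM or more. All SAM libraries share 1 block of library numbers, which may also give like effects: the 0 SAM-free libraries inside the block leave separate handling of the SAM libraries open.

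Genes that TGFβ raises were lower in SAM than in control. Here too, separate handling of the SAM libraries cannot be told apart from SAM itself. Of 375 genes raised by TGFβ on the NAM background, 307 passed the low-count filter in the libraries tested here. They had a median of -0.59 in SAM against control (camera adjusted p = 1.39e-19, and adjusted p = 0.000976 with an estimated correlation). The 469 tested of 471 lowered genes had 0.17 (camera adjusted p = 0.000934, and adjusted p = 0.0078 with an estimated correlation). Both calls kept their direction under the alternatives tried, with smaller medians of -0.171 and 0.095 without a fold limit. In NAM against control, the 390 genes raised by TGFβ on the SAM background had -0.01 (camera adjusted p = 0.84) and the 631 lowered genes -0.03 (camera adjusted p = 0.215).

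As NAM and SAM are both substrates of NNMT, both supplements acting on one set of genes in opposite directions was tested as a hypothesis. The higher of both correlations across genes between arms that share no library was 0.02, not the clearly negative value predicted for opposite action. This test cannot decide the question. NAM against control called 1 gene, and the NAM effects with and without TGFβ correlated with each other at only 0.12. An opposite SAM effect could therefore hardly give a clearly negative value. Mitochondrial transcripts made up 9.55% of gene reads in control, 7.24% in TGFβ, 8.63% in NAM, 6.86% in TGFβ+NAM, 10.3% in SAM and 7.17% in TGFβ+SAM. Of 45 pairs of libraries with like replicate number, 0 had deviations correlated above 0.1 across all tested genes, and 6 of 18 libraries stood closest to their own number. Across genes at 50 CPM or more, 8 of 45 pairs did, with a range of -0.402 to 0.354, and 8 of 18 libraries stood closest to their own number.

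The splits of 6 libraries into 3 against 3 number 10, the real one included, too few for a share under 0.05. Each other split mixes libraries of both groups, so a real difference adds to the spread within its groups. Where groups differ, low counts of the other splits follow from this construction. They do not measure how many genes chance would call. The real split, 1 of 10 as large in each case, and the highest other gave 2619 and 0 genes for TGFβ against control, 1 and 0 for NAM against control, 1591 and 0 for SAM against control and 11 and 1 for TGFβ+NAM against TGFβ. They gave 986 and 8 for TGFβ+SAM against TGFβ, 2946 and 0 for TGFβ+NAM against NAM, 3824 and 1 for TGFβ+SAM against SAM and 1097 and 1 for TGFβ+NAM against TGFβ+SAM. For the NAM interaction, with 0 genes by edgeR, splits say nothing about chance, since all 40 of 40 must give at least 0; the highest other gave 1.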
